A study of Homo sapiens with 24 samples.

How the data were processed

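RNA from LNCaP and PC3 cells was measured by RNA sequencing in 24 libraries, 2 for each of 12 groups, prepared with the NEBNext Ultra RNA kit and sequenced on a HiSeq4000, per the labels' protocols. The submitters' processing notes name STAR for alignment and hg38 as the genome, with no versions. The authors deposited RPKM values, per kilobase of gene and per unit of sequenced reads, for the 3 LNCaP sets, each normalized separately. For the PC3 set the authors deposited FPKM values, made in the same way from fragments. The sources used here do not state which reads the scaling counted, which annotation and counter were used, or whether counting was strand specific. Each set held 32 genes with no values, which were left out. In the PC3 set, 4 entries shared a gene symbol with another, and 28 symbols had turned into dates, against 26 in the HDAC set.

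Expression was tested within each set with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) on log2 of the deposited value plus 0.5, with a variance trend, for genes with a value of at least 1 in at least 2 libraries. Fold changes on this scale understate those of genes with low values. All groups of a set entered a single fit, and the p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 10 comparisons were each knockdown against its control, each rescue against the knockdown, the rescues against each other, added HOXB13 with and without shHDAC1/3, and the interaction of these. For 33 gene lists written beforehand, camera (limma) gave the list tests with a preset correlation of 0.01 and, as an alternative, with an estimated one, and lists with fewer than 5 tested members were not tested. Counts of list members were made over all genes and again adjusted over the list alone. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Gene positions came from the GENCODE annotation of GRCh38.

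The groups, comparisons, gene lists and most alternatives were fixed before the data were examined, as was the rule on which genes are named. Per comparison it took HOXB13, HDAC1 and HDAC3, then the 8 called genes with the highest and the 8 with the lowest log2 fold change (5 and 5 for the interaction). The latter needed groups that did not overlap and a mean of at least 2 in 1 group, and uncharacterized, noncoding and pseudogene symbols were passed over. It also took up to 4 members with the smallest p of each list described, then FASN, ACACA, ACLY, SCD, SREBF1 and SREBF2 for lipid metabolism and KLK3 and TMPRSS2 as prostate genes. Some genes and lists that were tested are not reported here. MIR30A fell outside the rule and was chosen after its values were seen.

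Whole reads were recovered from the deposited values by the common step of each gene's values, within 0.02 reads of a whole number. This succeeded for 23224 of 23243 genes (99.92%), those listed in all 4 sets with a value above 0 in at least 1 library. The same search on 500 genes whose values had been moved at random by a small amount found whole reads for 22. These 500 were drawn from genes with a mean of at least 1. The reads in genes per library ranged from 6249316 to 13884629 and are given in the report by set. The recovered reads served to measure depth, to compare replicates with counting noise and to run limma-voom as an alternative.

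The tests were tried on simulated data with 50 genes changed at each of 4 fold sizes. At 1.5-fold, 39 of 50 were recovered for the LNCaP knockdown (12307 genes), 37 for shHDAC1/3 (12666 genes), 13 for the hormone-starved knockdown (12284 genes) and 18 for PC3 (12296 genes). At 2-fold these were 48, 48, 39 and 47. False calls made up 16.9%, 9.6%, 25.5% and 13% of the calls, above the nominal 5% in each, and 0, 0, 0 and 1 of the 27, 27, 27 and 29 lists tested were called.

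The alternatives tried were pseudocounts of 0.1 and 1, no filter on low values, quantile normalization, scaling to equal median ratios, no variance trend, only the groups compared in the fit, the replicate number as a covariate, and each library left out in turn, with limma-voom and the spread per gene of the hormone-starved libraries added after the data were seen. For comparisons that share the shHOXB13 libraries, the covariance of the log2 fold changes was compared with 20 simulations in which the rescue group did not differ from the knockdown.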

Results

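Gene expression was measured by RNA sequencing in 24 libraries of 2 human prostate cancer cell lines. LNCaP cells gave 20 libraries and PC3 cells gave 4. The libraries formed 12 groups of 2. Cells were infected with lentiviral vectors that carried a control (pGIPZ or plko.1), short hairpin RNAs against HOXB13 (shHOXB13) or against HDAC1 and HDAC3 together (shHDAC1/3), or these with added HOXB13, either wild type (WT) or with the G84E substitution. HOXB13 encodes a homeodomain transcription factor of the prostate lineage, and HDAC1 and HDAC3 encode histone deacetylases. The series concerns the part that HOXB13 and HDAC3 play in the control of lipid metabolism genes. Cells were harvested 7 days after infection, except for a hormone-starved LNCaP set kept 4 days after infection and then 3 days in hormone-depleted medium. The 4 sets were normalized separately, so each comparison stayed within a set. The reads assigned to genes ranged from 6249316 to 13884629 per library and were lowest in the LNCaP pGIPZ and shHOXB13 libraries, at 6249316 to 6821846. Values below are means ± SD of n = 2 libraries in RPKM (FPKM for PC3), and log2 fold changes are given ± standard error. The labels do not state that the 2 libraries of a group came from separate cultures, except for the hormone-starved set, which they describe as replicate experiments. The p-values therefore measure only the spread between these libraries, which may be technical. Replicates of the knockdown and rescue set differed by a chi-square per degree of freedom of 1.20 to 1.24, where 1.00 is counting noise alone, and those of the HDAC set by 1.36 to 1.48. In the hormone-starved set the value was 3.61 for pGIPZ and 5.50 for shHOXB13, and in PC3 it was 5.99 for pGIPZ and 1.85 for shHOXB13.

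The targeted genes were examined in every library before any other gene. HOXB13 (chromosome 17, 48724763 to 48729178 on GRCh38) fell from 91.1 ± 0.3 RPKM with pGIPZ to 38.5 ± 0.8 with shHOXB13 in LNCaP cells, leaving 42.2% (log2 fold change -1.23 ± 0.027, adjusted p = 1.3e-07). The added wild type gene brought it to 105 ± 1.2 RPKM and the G84E form to 98.05 ± 1.2 RPKM. No reads or vector sequences were at hand, so added and endogenous HOXB13 could not be told apart. In the HDAC set, HDAC1 (chromosome 1, 32292086 to 32333635) fell from 78.7 ± 0.01 to 25.1 ± 1.5 RPKM (-1.63 ± 0.053) and HDAC3 (chromosome 5, 141620876 to 141636870) from 25.1 ± 0.36 to 10.02 ± 0.17 RPKM (-1.28 ± 0.044) with shHDAC1/3. HOXB13 itself fell there as well (-0.71 ± 0.033), at 46.9 ± 2.0 against 76.9 ± 0.71 RPKM with plko.1. Added HOXB13 raised the gene to 192 ± 1.0 RPKM in the plko.1+HOXB13 libraries. In the libraries labelled shHDAC1/3+HOXB13 it reached only 53.5 ± 0.15 RPKM, below the plko.1 control, which goes against that label. HOXB13 fell from 85.6 ± 0.63 to 41.5 ± 1.8 RPKM in hormone-starved LNCaP cells and from 319.8 ± 9.8 to 213 ± 1.5 FPKM in PC3 cells, leaving 66.7% (-0.58 ± 0.075, adjusted p = 0.034). The PC3 call ended with no filter on low values, without the variance trend, and without shHOXB13 replicate 1 (-0.59) or replicate 2 (-0.58).

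**Figure D1:**
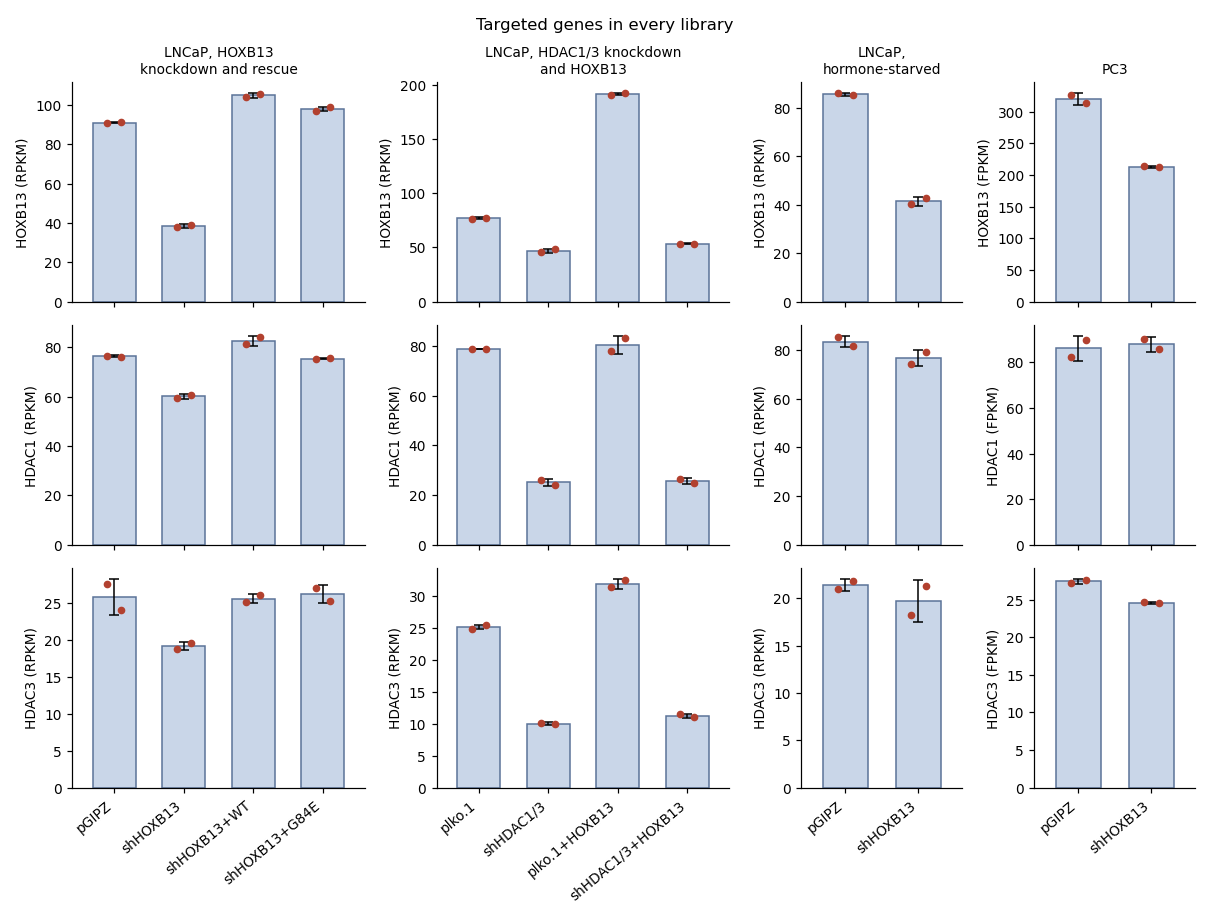
Values of HOXB13, HDAC1 and HDAC3 (vertical axes, RPKM, or FPKM for PC3) in the 12 groups of the 4 sets (horizontal axes), with bars for the mean of 2 libraries, whiskers for the SD and points for single libraries. HOXB13 stands at 38.5 RPKM with shHOXB13 against 91.1 with pGIPZ, and at 53.5 in the libraries labelled shHDAC1/3+HOXB13 against 192 in plko.1+HOXB13.

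The comparison of shHOXB13 with pGIPZ in LNCaP cells asked what the loss of HOXB13 did to expression, lipid genes included. FASN (chromosome 17, 82078333 to 82098332), which encodes fatty acid synthase, rose from 503 ± 2.4 to 1286 ± 6.0 RPKM (log2 fold change 1.35 ± 0.013, adjusted p = 7.9e-09). SCD (chromosome 10, 100347124 to 100364834), the stearoyl-CoA desaturase, rose from 180.3 ± 2.1 to 370.2 ± 3.8 RPKM (1.04 ± 0.019), and ACACA (chromosome 17, 37084988 to 37406818), which makes malonyl-CoA, from 34.4 ± 0.91 to 54.7 ± 0.5 RPKM (0.66 ± 0.033). Of the 20 fatty acid synthesis genes tested, 11 rose and 1 fell (camera adjusted p = 1.6e-06). SREBF1, the transcription factor that activates these genes, rose by 0.26 and ELOVL5 by 0.38. Of 20 cholesterol synthesis genes, 8 rose and 4 fell (adjusted p = 2.5e-04), among them TM7SF2 (0.98 ± 0.031) and FDFT1 (0.69 ± 0.026), both higher. In the list of SREBP pathway regulators, 9 of 13 rose and 1 fell (adjusted p = 3.4e-04), with SCAP at 0.60 ± 0.031.

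Genes of cell division fell together in the same knockdown. All 27 DNA replication genes tested fell (median log2 fold change -1.02, camera adjusted p = 2.7e-11), as did all 24 mitosis genes (median -1.18, adjusted p = 1.2e-11). MCM2, a subunit of the replicative helicase, went from 22.3 ± 0.09 to 8.5 ± 0.03 RPKM (-1.34 ± 0.043) and CCNB1, the cyclin of mitotic entry, from 39.4 ± 0.22 to 17.5 ± 0.03 RPKM (-1.15 ± 0.032). KLK3, which encodes prostate-specific antigen, rose from 1160.1 ± 21 to 2709 ± 6.0 RPKM (1.22 ± 0.013) and KLK2, a related kallikrein, by 0.95. The genes with the lowest log2 fold changes included PEG3 (-2.71 ± 0.044), the transcription factor MAF (-2.56 ± 0.039), the transmembrane protein TMEFF2 (-2.38 ± 0.073) and RFX6 (-2.38 ± 0.091). MSMB, which encodes a secreted prostate protein, rose from 2.1 ± 0.88 to 16.2 ± 0.1 RPKM (2.73 ± 0.41), and PLA2G4A, a cytosolic phospholipase, by 2.16 ± 0.14. The adjusted p of the called genes named in these comparisons of shHOXB13 with pGIPZ was at most 0.0014 by limma. The counts of the lists given here were identical when adjusted over the list alone.

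In all, 5851 of 12297 genes passed an adjusted p of 0.05 in the LNCaP knockdown, 1585 higher and 4266 lower. The median log2 fold change of all genes was -0.13, and after scaling to equal median ratios the split was 2653 higher and 2441 lower. Relative to that median, the log2 changes were 1.48 for FASN, 1.17 for SCD, 1.35 for KLK3, -1.21 for MCM2 and -2.58 for PEG3, and the list medians were 0.33 for fatty acid synthesis, -0.89 for DNA replication and -1.05 for mitosis. The 10 genes with the most reads took 5.75% and 5.77% of the reads in genes in the shHOXB13 libraries, where FASN had the most, against 3.52% in both pGIPZ libraries. Of the called genes, 147 were at least 2-fold higher and 299 at least 2-fold lower. With the spread per gene of the hormone-starved libraries in place of the set's own, 3121 genes passed, but not SREBF1.

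**Figure D2:**
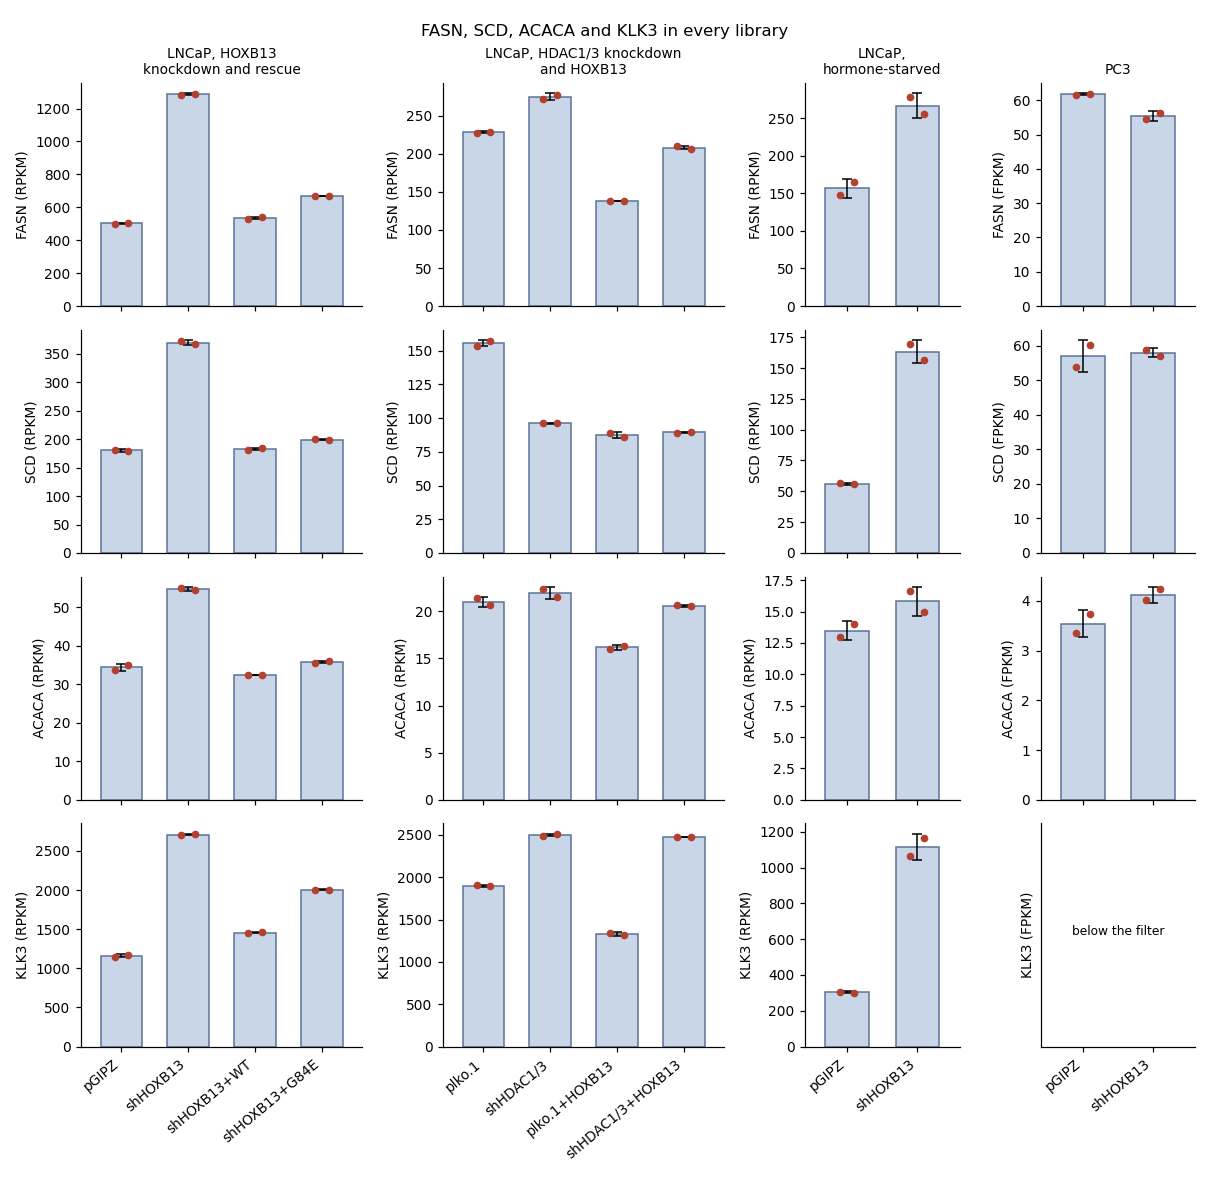
Values of FASN, SCD, ACACA and KLK3 (vertical axes, RPKM, or FPKM for PC3) in the 12 groups of the 4 sets (horizontal axes), with bars for the mean of 2 libraries, whiskers for the SD and points for single libraries. FASN stands at 1286 RPKM with shHOXB13, against 503 with pGIPZ, 534 with added WT and 669 with added G84E, and KLK3 did not reach the minimum value for testing in PC3.

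Wild type HOXB13 or its G84E form was added to the knockdown to ask which changes each reversed. FASN fell to 534 ± 6.9 RPKM with WT (-1.27 ± 0.013) and to 669 ± 0.84 RPKM with G84E (-0.94 ± 0.013). SCD had a log2 fold change of -1.01 ± 0.019 with WT and -0.89 ± 0.019 with G84E, and ACACA of -0.74 ± 0.033 and -0.61 ± 0.033. ACLY, which makes acetyl-CoA, had changed little with shHOXB13 (0.09 ± 0.019, adjusted p = 0.0076), and it fell with WT (-0.15 ± 0.019, adjusted p = 4.8e-04) but was higher with G84E (0.07 ± 0.019, adjusted p = 0.014), where its direction turned after scaling to equal median ratios (-0.09). The ACLY call with shHOXB13 ended under quantile normalization (0.06), those with shHOXB13 and G84E without the variance trend, and all of them with the spread of the hormone-starved libraries. In the fatty acid synthesis list, 12 of 20 genes fell and 6 rose with WT (camera adjusted p = 1.4e-06), and 12 fell and 5 rose with G84E (adjusted p = 8.6e-06; 13 and 5 adjusted over the list alone, and unchanged for WT). After scaling to equal median ratios 14 of these genes fell and 1 rose with WT, and 14 and 1 with G84E. All 27 DNA replication genes and all 24 mitosis genes rose with either form, with medians of 1.04 and 1.24 for WT and 0.83 and 1.05 for G84E (highest camera adjusted p = 3.3e-08), over all genes and adjusted over the list alone. Some genes went past their level with pGIPZ. PEG3 rose to 32.1 ± 0.51 RPKM with WT (3.87 ± 0.044) and 42.3 ± 0.42 RPKM with G84E (4.26 ± 0.044), against 14.1 ± 0.27 with pGIPZ. The amine oxidase gene AOC1 rose from 0.17 ± 0.11 RPKM to 12.3 ± 1.2 (4.27 ± 0.13) and 29.6 ± 0.85 RPKM (5.50 ± 0.13), against 0.050 with pGIPZ, and the zinc transporter gene SLC30A4 from 9.66 ± 0.18 to 85.9 ± 0.37 and 83.6 ± 1.8 RPKM (3.09 ± 0.033 and 3.05 ± 0.033), against 28.5 ± 0.30 with pGIPZ. AGR2, which encodes a protein disulfide isomerase, fell from 559.8 ± 2.9 to 85.9 ± 4.0 (-2.70 ± 0.031) and 85.7 ± 0.12 RPKM (-2.70 ± 0.031). UGT2B11 and UGT2B28, near-identical glucuronosyltransferase genes whose reads cannot be separated with certainty, had log2 fold changes of -2.87 ± 0.043 and -2.88 ± 0.069 with WT. KLK3 fell from 2709 ± 6.0 to 1454 ± 7.7 RPKM with WT (-0.90 ± 0.013) and to 2003 ± 6.2 with G84E (-0.44 ± 0.013), but neither call held under quantile normalization, and the G84E value was then -0.07. The adjusted p of the other genes named here was at most 2.9e-06 with WT and 8.5e-06 with G84E.

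Against shHOXB13, 6642 genes passed the test with WT, 5179 higher and 1463 lower, and 6245 with G84E, 4629 higher and 1616 lower. The median log2 fold change of all genes was 0.18 with WT and 0.16 with G84E, and after scaling to equal median ratios the splits were 2585 higher and 2804 lower, and 2661 higher and 2920 lower. Relative to these medians, FASN stood at -1.45 and -1.10, PEG3 at 3.69 and 4.11, and the fatty acid synthesis list at -0.38 and -0.36. Of the 5851 genes called in the knockdown, 4520 (77.3%) were called in the opposite direction with WT and 3937 (67.3%) with G84E. Independent lists of these sizes would share 1985.2 and 1814.2 genes. The covariance of the log2 fold changes was -0.165 with WT, against -0.015 in 20 simulations with unchanged rescue groups, and -0.147 with G84E, against -0.015. Part of the excess may come from the shHOXB13 libraries that the comparisons shared. The simulations drew only the spread between the libraries of a group. A deviation common to both shHOXB13 libraries is absent from them, so they do not bound this part. With the spread of the hormone-starved libraries the changed genes were 4065 with WT and 3730 with G84E, and the genes reversed 2289 and 1912.

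The G84E and WT rescues were then compared directly, to ask whether the substitution changed what added HOXB13 did. HOXB13 itself was at 98.05 ± 1.2 RPKM with G84E and 105 ± 1.2 RPKM with WT (log2 fold change -0.10 ± 0.027, adjusted p = 0.065), a difference that passed only by limma-voom (-0.07). Genes of the hypoxia response were higher with G84E, 12 of 16 (median 0.45, camera adjusted p = 8.3e-19), with none lower. The list had also risen with shHOXB13 against pGIPZ, 9 higher and 3 lower (adjusted p = 2.5e-04). Against shHOXB13 it fell with WT, 10 lower and 1 higher (adjusted p = 2.8e-07). It did not pass with G84E against shHOXB13, 9 higher and 5 lower (adjusted p = 0.83). Its medians against pGIPZ were 0.261 with shHOXB13, 0.055 with WT and 0.53 with G84E. VEGFA, the vascular growth factor gene, was at 153 ± 1.1 RPKM with G84E against 97.6 ± 1.2 with WT (0.65 ± 0.026) and BNIP3 at 270.4 ± 6.7 against 189 ± 5.2 RPKM (0.52 ± 0.03). Of 16 glycolysis genes 12 were higher and 1 lower (adjusted p = 8.1e-16), among them PGK1 (0.54 ± 0.015) and LDHA (0.34 ± 0.017). These counts were identical when adjusted over the list alone. NDUFA4L2, a mitochondrial protein gene, was at 129 ± 2.9 against 63.1 ± 1.6 RPKM (1.02 ± 0.034) and the lysyl hydroxylase gene PLOD2 at 13.9 ± 0.11 against 6.48 ± 0.23 (1.04 ± 0.076). ID1 and ID3, which encode inhibitors of DNA-binding factors, were lower with G84E (-1.26 ± 0.088 and -0.91 ± 0.06). FASN was higher with G84E (0.33 ± 0.013), as was KLK3 (0.46 ± 0.013), whose direction turned under quantile normalization (-0.07). In the fatty acid synthesis list, 4 of 20 genes were higher and 1 lower, over all genes and adjusted over the list alone (median -0.005, mean 0.014, camera adjusted p = 0.065), and the median was 0.032 under quantile normalization, where the list passed as higher. Of 20 cholesterol synthesis genes 7 were lower with G84E (8 adjusted over the list alone) and none higher (adjusted p = 6.1e-05, but adjusted p = 0.054 with an estimated correlation). The adjusted p of the called genes named here was at most 5.7e-04. In all, 1158 of 12297 genes differed, 371 higher and 787 lower with G84E (448 and 462 after scaling to equal median ratios). The count was 237 without shHOXB13+WT replicate 1, 257 without shHOXB13+WT replicate 2, 239 without shHOXB13+G84E replicate 1 and 201 without shHOXB13+G84E replicate 2, and 23 with the spread of the hormone-starved libraries, where FASN, KLK3, BNIP3, PGK1, LDHA, PLOD2 and ID3 did not pass. Over 12297 genes, the log2 fold changes of the knockdown, which shares no library with this comparison, had a Pearson r of 0.16 (Spearman rho 0.23) with those between G84E and WT.

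Knockdown of HDAC1 and HDAC3 in LNCaP cells was compared with plko.1 to ask which genes the deacetylases controlled. HOXB13 fell in the same libraries (-0.71 ± 0.033, limma adjusted p = 4.7e-06), so the changes cannot be assigned to the deacetylases alone. Mitosis genes fell, all 24 of them (median -1.64, camera adjusted p = 1.0e-09), and 25 of 27 DNA replication genes (median -0.97, adjusted p = 3.1e-07, but adjusted p = 0.11 with an estimated correlation). BIRC5, the survivin gene, went from 8.54 ± 0.47 to 1.51 ± 0.1 RPKM (-2.17 ± 0.10) and NUSAP1 from 13.9 ± 0.46 to 2.57 ± 0.15 RPKM (-2.23 ± 0.073). AGR2 rose from 68.95 ± 4.2 to 355 ± 3.6 RPKM (2.36 ± 0.039) and UGT2B11, uncertain as above, from 32.04 ± 0.7 to 196 ± 3.3 RPKM (2.59 ± 0.032). FASN rose from 228 ± 1.3 to 275 ± 4.6 RPKM (0.27 ± 0.019), while SCD fell from 155 ± 2.3 to 96.1 ± 0.18 (-0.69 ± 0.026) and SREBF2, the regulator of cholesterol synthesis, from 36 ± 0.8 to 18.98 ± 0.05 (-0.91 ± 0.039). ACACA had a log2 fold change of 0.06 ± 0.042 (adjusted p = 0.26), which passed the test at 0.19 after scaling to equal median ratios. Of the 20 fatty acid synthesis genes 4 rose and 11 fell, over all genes and adjusted over the list alone, and the list as a whole passed only with no filter on low values (adjusted p = 0.16 with the filter). Of 16 glycolysis genes 13 fell and 1 rose (adjusted p = 2.0e-05, but adjusted p = 0.10 with an estimated correlation), including ALDOA (-0.58 ± 0.015). KLK3 rose (0.39 ± 0.012), though not under quantile normalization, and the membrane protein gene TMEFF2 fell from 15.9 ± 0.36 to 2.39 ± 0.26 RPKM (-2.50 ± 0.07). Of 5 fibroblast markers tested, 3 collagen genes were higher, COL1A1 (0.52 ± 0.054), COL6A1 (0.22 ± 0.026) and COL6A2 (0.35 ± 0.039) (adjusted p = 0.0067, but adjusted p = 0.13 with an estimated correlation), a list that did not pass with no filter on low values either. The list counts of this comparison were identical when adjusted over the list alone, and the adjusted p of the called genes was at most 3.7e-04. In all, 6393 of 12697 genes changed, 2002 higher and 4391 lower. The median of all genes was -0.12, against which FASN stood at 0.38, SCD at -0.57 and the mitosis list at -1.52. Scaling to equal median ratios gave 3017 higher and 2992 lower, and the spread of the hormone-starved libraries gave 3817 genes, without FASN and COL6A1.

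HOXB13 was added to plko.1 control cells to ask what more of the factor did. FASN fell from 228 ± 1.3 to 138 ± 0.15 RPKM (-0.73 ± 0.019), SCD from 155 ± 2.3 to 87.6 ± 2.1 (-0.82 ± 0.026), SREBF1 from 134 ± 0.87 to 92.3 ± 1.8 (-0.53 ± 0.027) and ACACA from 21.01 ± 0.55 to 16.2 ± 0.26 RPKM (-0.37 ± 0.042). In the fatty acid synthesis list 7 of 20 genes fell and 4 rose (9 and 5 adjusted over the list alone; camera adjusted p = 5.8e-05, but adjusted p = 0.072 with an estimated correlation). Of 19 interferon-stimulated genes 16 fell and none rose (18 adjusted over the list alone; median -0.70, adjusted p = 1.7e-17). IFIT3, an antiviral effector, went from 10.7 ± 0.42 to 3.11 ± 0.18 RPKM (-1.63 ± 0.063) and the interferon-induced chemokine CXCL10 from 13.8 ± 0.1 to 2.49 ± 0.23 RPKM (-2.25 ± 0.061). Of 9 NF-kB targets 6 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 1.2e-06, but adjusted p = 0.072 with an estimated correlation), BIRC3 among them (-1.78 ± 0.046). KLK3 fell (-0.52 ± 0.012), as did the protease gene TMPRSS2 (-0.46 ± 0.017), although TMPRSS2 had risen when WT (0.30 ± 0.019, adjusted p = 1.6e-05) or G84E (0.55 ± 0.019, adjusted p = 8.9e-07) was added to the HOXB13 knockdown. Relative to the median of all genes, those rises were 0.11 with WT and 0.39 with G84E. TMPRSS2 had also risen with shHOXB13 itself (0.27 ± 0.019, limma adjusted p = 3.6e-05). Of 13 interferon-stimulated genes tested in that set, 3 rose and 3 fell with shHOXB13 (camera adjusted p = 0.067). Against shHOXB13, 3 rose and 3 fell with WT (adjusted p = 0.036, but adjusted p = 0.13 with an estimated correlation). With G84E 2 rose and 5 fell (adjusted p = 0.052). AOC1 rose from 1.32 ± 0.16 to 62.03 ± 0.74 RPKM (5.10 ± 0.081) and RPE65, the retinoid isomerase gene, from 0.07 ± 0 to 10.8 ± 0.54 RPKM (4.31 ± 0.16). The calcium-binding protein gene S100P fell from 89 ± 2.8 to 13.3 ± 0.72 RPKM (-2.70 ± 0.071). The adjusted p of the genes named here was at most 8.5e-04. In all, 4042 genes changed, 3018 higher and 1024 lower, with a split of 1546 higher and 1538 lower after scaling to equal median ratios. The count was 2472 without plko.1 replicate 1, 2589 without plko.1 replicate 2, 2568 without plko.1+HOXB13 replicate 1 and 2551 without plko.1+HOXB13 replicate 2, and 994 with the spread of the hormone-starved libraries, without ACACA.

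Adding HOXB13 to cells with shHDAC1/3, and the interaction of both treatments, were meant to ask whether the effect of HOXB13 differed when the deacetylases were low. As given above, HOXB13 differed little between these groups, 53.5 ± 0.15 in the libraries labelled shHDAC1/3+HOXB13 and 46.9 ± 2.0 RPKM in shHDAC1/3 (0.19 ± 0.033, adjusted p = 0.044), so any direction drawn from them rests on that small gain. The HOXB13 call ended when any 1 of the 8 libraries of the set was left out, with log2 fold changes from 0.15 without shHDAC1/3 replicate 1 to 0.23 without shHDAC1/3 replicate 2. FASN was lower in the libraries labelled shHDAC1/3+HOXB13, 208 ± 2.0 against 275 ± 4.6 RPKM (-0.40 ± 0.019, adjusted p = 4.5e-04). SCD had a log2 fold change of -0.10 ± 0.026 (adjusted p = 0.12) and KLK3 of -0.01 ± 0.012 (adjusted p = 0.64), and these passed only by limma-voom, at -0.11 and -0.02. Of 20 fatty acid synthesis genes 2 were lower and none higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.053), and the list passed after scaling to equal median ratios, by limma-voom or without shHDAC1/3 replicate 1, with medians of -0.074, -0.074 and -0.054. In all, 204 genes passed, 111 higher and 93 lower. The count was 121 without plko.1 replicate 1, 124 without plko.1 replicate 2, 29 without shHDAC1/3 replicate 1, 21 without shHDAC1/3 replicate 2, 124 without plko.1+HOXB13 replicate 1, 124 without plko.1+HOXB13 replicate 2, 59 without shHDAC1/3+HOXB13 replicate 1 and 27 without shHDAC1/3+HOXB13 replicate 2, 6 with the spread of the hormone-starved libraries, without FASN, 11 without the variance trend, again without FASN, and 14 with only these 2 groups in the fit.

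The interaction compared the log2 difference between the libraries labelled shHDAC1/3+HOXB13 and shHDAC1/3 with that between plko.1+HOXB13 and plko.1, and 1766 genes passed, 522 with a higher and 1244 with a lower difference for shHDAC1/3 (729 and 566 after scaling to equal median ratios). HOXB13 itself had an interaction of -1.12 ± 0.046, and at 53.5 ± 0.15 RPKM it was lower in the libraries labelled shHDAC1/3+HOXB13 than in plko.1 (76.9 ± 0.71), so these values do not show what added HOXB13 does in shHDAC1/3 cells. AOC1, which rose with HOXB13 added to plko.1 cells, was at 2.34 ± 0.17 RPKM in the libraries labelled shHDAC1/3+HOXB13 against 1.7 ± 0.03 in shHDAC1/3 (interaction -4.73 ± 0.12), and RPE65 differed likewise (-3.57 ± 0.22). FASN (0.33 ± 0.028) and SCD (0.72 ± 0.036) were lower by less there, and 6 of 20 fatty acid synthesis genes had a higher and none a lower difference (7 and 3 adjusted over the list alone; camera adjusted p = 8.4e-05, but adjusted p = 0.098 with an estimated correlation). Of 19 interferon-stimulated genes 12 had a higher difference (14 adjusted over the list alone; median 0.70, adjusted p = 2.1e-14). KLK3 had an interaction of 0.50 ± 0.016 and S100P of 2.22 ± 0.1. The adjusted p of these genes was at most 6.6e-04. Across 12697 genes, which are not independent replicates, the differences with plko.1 and with shHDAC1/3 had a Pearson r of 0.18 and a Spearman rho of 0.22. The interaction count was 880 without plko.1 replicate 1, 928 without plko.1 replicate 2, 1105 without shHDAC1/3 replicate 1, 1041 without shHDAC1/3 replicate 2, 943 without plko.1+HOXB13 replicate 1, 991 without plko.1+HOXB13 replicate 2 and 1075 without shHDAC1/3+HOXB13 replicate 2, and 150 with the spread of the hormone-starved libraries, without FASN and KLK3.

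**Figure D3:**
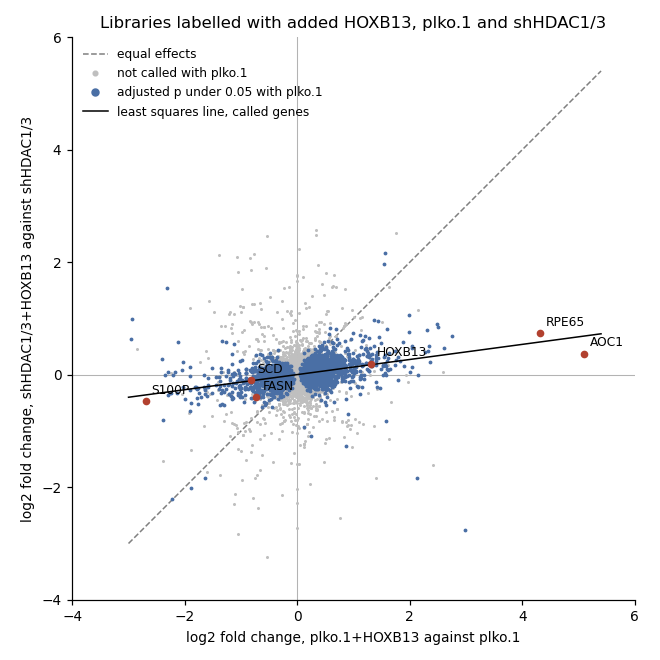
Log2 fold change of each tested gene with added HOXB13 in plko.1 cells (horizontal axis) and in the libraries labelled shHDAC1/3+HOXB13 against shHDAC1/3 (vertical axis), with blue points for the 4042 genes past an adjusted p of 0.05 with plko.1, a solid least squares line through these and a dashed line of equal effects. FASN lies at -0.73 and -0.40 on the horizontal and vertical axes, and HOXB13 at 1.31 and 0.19.

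The knockdown was repeated in hormone-starved LNCaP cells to ask which changes occurred without hormone. KLK3 rose from 303 ± 4.8 to 1115 ± 71 RPKM (1.88 ± 0.096) and KLK2 from 17.5 ± 2.0 to 104 ± 1.9 RPKM (2.54 ± 0.095), while ACPP, which encodes prostatic acid phosphatase, fell from 24.3 ± 3.0 to 5.14 ± 0.15 RPKM (-2.13 ± 0.11). SCD rose from 56.2 ± 0.74 to 163 ± 9.4 RPKM (1.53 ± 0.081) and FASN from 157 ± 13 to 267 ± 16 RPKM (0.77 ± 0.095), the latter not past the test with no filter on low values. Of 19 fatty acid synthesis genes 5 rose and none fell (adjusted p = 0.0010, but adjusted p = 0.50 with an estimated correlation). Of 20 cholesterol synthesis genes 5 rose and none fell (8 adjusted over the list alone; adjusted p = 1.3e-04, but adjusted p = 0.50 with an estimated correlation). The immunoglobulin receptor gene PIGR rose from 8.83 ± 0.04 to 56.7 ± 1.8 RPKM (2.62 ± 0.081) and TM4SF1 from 7.27 ± 1.6 to 55.8 ± 0.49 RPKM (2.87 ± 0.14). The kinase inhibitor gene CAMK2N1 fell from 342 ± 0.33 to 36.1 ± 0.5 RPKM (-3.23 ± 0.076) and the secreted phospholipase gene PLA2G2A from 1158 ± 25 to 131 ± 16 (-3.15 ± 0.11). None of 20 mitosis genes or of 25 DNA replication genes passed the limma test, over all genes or adjusted over the list alone, with medians of -0.17 and 0.03, though the replication list passed as higher under quantile normalization (0.139). Of 6 fibroblast markers 2 fell, COL1A1 (-0.55 ± 0.10) and COL6A1 (-0.38 ± 0.083) (4 adjusted over the list alone; adjusted p = 0.015, but adjusted p = 0.52 with an estimated correlation). The list did not pass without pGIPZ replicate 2 (median -0.28) or shHOXB13 replicate 1 (-0.26). COL1A1 and COL6A1 did not pass without pGIPZ replicate 2 (-0.44 and -0.34) or shHOXB13 replicate 2 (-0.51 and -0.34), nor did COL6A1 without pGIPZ replicate 1 (-0.42). The counts of the fatty acid synthesis list were identical when adjusted over the list alone, and the adjusted p of the genes named was at most 0.033. In all, 1181 of 12380 genes changed, 488 higher and 693 lower (678 and 460 after scaling to equal median ratios). The count was 522 without pGIPZ replicate 1, 509 without pGIPZ replicate 2 and 395 without shHOXB13 replicate 2, 291 with no filter and 2796 by limma-voom on the recovered reads.

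In PC3 cells the same knockdown asked what HOXB13 did in a second line. TGM2, which encodes a transglutaminase, rose from 13.96 ± 0.88 to 37.7 ± 0.79 FPKM (1.40 ± 0.078) and the phosphatase gene PTPN5 from 3.49 ± 0.22 to 13.2 ± 1.1 (1.77 ± 0.10). ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell from 43.2 ± 7.7 to 20.2 ± 0.69 FPKM (-1.07 ± 0.12). Of 24 interferon-stimulated genes 6 rose and none fell (18 adjusted over the list alone; median 0.46, camera adjusted p = 6.4e-13, but adjusted p = 0.45 with an estimated correlation), among them the antiviral gene MX1 (0.55 ± 0.068), which did not pass without pGIPZ replicate 1 (0.58), shHOXB13 replicate 1 (0.57) or shHOXB13 replicate 2 (0.54). Fatty acid genes did not pass the test. FASN was at 61.7 ± 0.25 with pGIPZ and 55.4 ± 1.4 FPKM with shHOXB13 (-0.15 ± 0.067, adjusted p = 0.26), SCD had a log2 fold change of 0.03 ± 0.08 (adjusted p = 0.88), and none of the 18 list members passed, over all genes or adjusted over the list alone (camera adjusted p = 0.53). The adjusted p of the called genes was at most 0.030. In all, 118 of 12339 genes changed, 70 higher and 48 lower (49 and 35 after scaling to equal median ratios). The count was 22 without pGIPZ replicate 1, 1838 without pGIPZ replicate 2 and 71 without shHOXB13 replicate 1, 937 by limma-voom on the recovered reads, 1 without the variance trend, and 0 by limma with no filter on low values, where 2769 genes had an unadjusted p under 0.05. None of the PC3 genes named here passed with no filter on low values or without the variance trend.

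**Figure D4:**
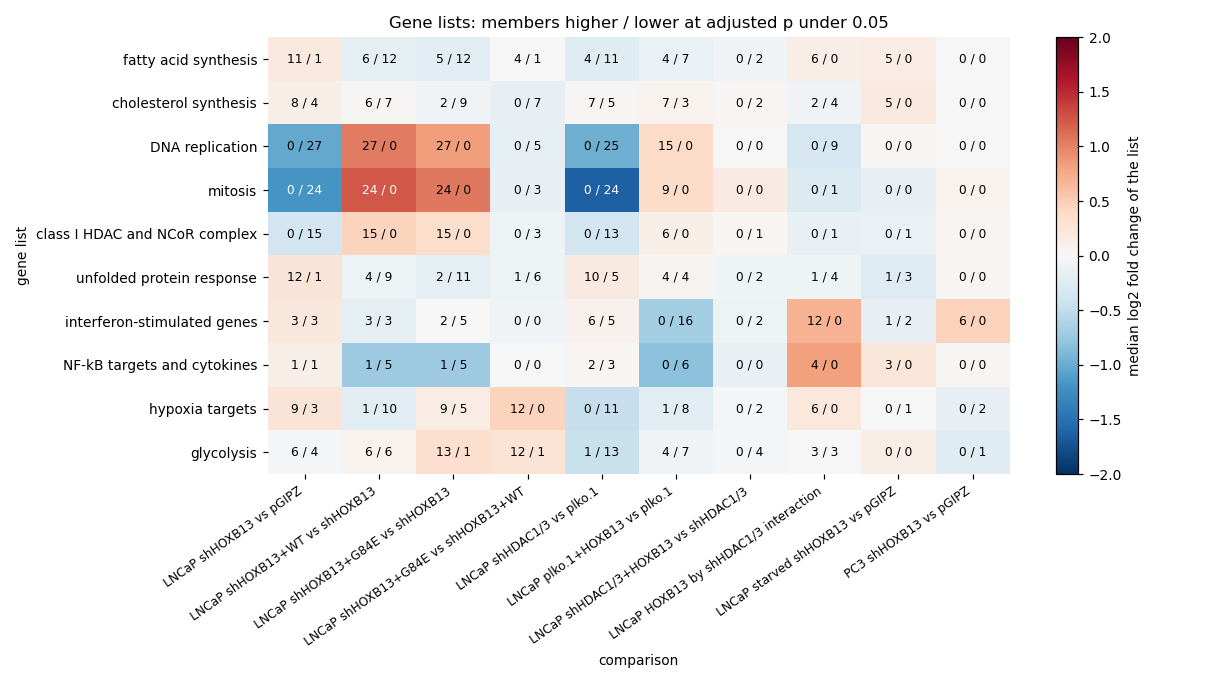
Median log2 fold change (colour) of 10 gene lists (vertical axis) in the 10 comparisons (horizontal axis), with the number of members higher and lower at an adjusted p under 0.05 written in each cell. All 24 mitosis genes were lower in the LNCaP knockdown and higher with added WT or G84E, and 16 of 19 interferon-stimulated genes were lower with HOXB13 added to plko.1 cells.

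The effects were also compared across sets, over genes tested in both, where genes are not independent replicates and no p was computed. The LNCaP knockdown and the hormone-starved knockdown had a Pearson r of 0.24 (Spearman rho 0.15) over 11599 genes, with 207 genes called higher in both, where independent lists would share 57.4, and 283 lower in both, where they would share 221. FASN, SCD and KLK3 were higher in both. The LNCaP and PC3 knockdowns had an r of -0.07 (rho -0.09), with 3 genes higher in both (3.7 for independent lists) and 8 lower in both (10.8). The hormone-starved and PC3 knockdowns had an r of -0.19 (rho -0.29), with 2 genes higher in both (1.1 for independent lists), 7 lower in both (1.6) and 3 and 2 in opposite directions (1.1 and 1.6). The LNCaP knockdown and the addition of HOXB13 to plko.1 cells had an r of -0.24 (rho -0.21), with 374 genes higher in the knockdown and lower with added HOXB13 (123 for independent lists) and 1402 the other way (1042). FASN, SCD, ACACA and KLK3 were among the genes higher in the knockdown and lower with added HOXB13. The knockdowns of HOXB13 and of HDAC1 and HDAC3 had an r of 0.27 (rho 0.21), with 493 genes higher in both (241 for independent lists) and 2048 lower in both (1517). FASN and KLK3 were higher in both, and all 24 mitosis genes were lower in both. SCD was higher with shHOXB13 (1.04) but lower with shHDAC1/3 (-0.69), and ACACA passed only with shHOXB13. In the fatty acid synthesis list 11 genes rose and 1 fell with shHOXB13, while 4 rose and 11 fell with shHDAC1/3. HOXB13 itself fell with shHDAC1/3 too (-0.71), so shared changes cannot be assigned to the deacetylases or to HOXB13. The differences between sets were not tested.

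Of the list calls given above, those that held with an estimated correlation between genes were fatty acid synthesis, cholesterol synthesis, SREBP pathway regulators, DNA replication and mitosis in the LNCaP knockdown (highest adjusted p = 0.038), fatty acid synthesis, DNA replication and mitosis in both rescues (0.037), hypoxia targets and glycolysis between G84E and WT (0.011), mitosis with shHDAC1/3 (0.0496), and interferon-stimulated genes with HOXB13 added to plko.1 cells (0.017) and in the interaction (0.017). Hypoxia targets held as well with shHOXB13 (0.037) and with WT (0.032). None of those given held in the hormone-starved or PC3 knockdowns. This alternative also uses the residual degrees of freedom of the fit, 2 in these sets and 4 in the others. For mitosis in the LNCaP knockdown, the estimated correlation of -0.006 lay below the preset 0.01. Its camera p still went from 4.5e-13 to 0.0013. A lost call therefore cannot be assigned to correlation between genes, and with 2 degrees of freedom little could pass.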

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

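All tests of causes in this part were chosen only after the results were seen, while the interaction itself was planned. A test of the interaction flagged 1766 genes, for which the log2 difference between plko.1+HOXB13 and plko.1 was not that between the libraries labelled shHDAC1/3+HOXB13 and shHDAC1/3. It differed for HOXB13 itself (-1.120), AOC1 (-4.732), RPE65 (-3.574), S100P (2.223), SCD (0.721), KLK3 (0.503) and FASN (0.328). It differed as well in the medians of the interferon-stimulated genes (0.699) and the fatty acid synthesis genes (0.128), though the latter did not hold (adjusted p = 0.098 with an estimated correlation). FASN was lower with shHOXB13 in both PC3 libraries (-0.155), a difference that did not pass the test (adjusted p = 0.26), while it was higher in both shHOXB13 libraries of the LNCaP knockdown and of the hormone-starved knockdown. These opposite directions of FASN between sets were not tested.

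Fewer genes changed with HOXB13 in the libraries labelled shHDAC1/3+HOXB13 than in plko.1+HOXB13, 204 against 4042. Lower depth of the shHDAC1/3 libraries is argued against, since depth adds noise and leaves folds in place, but the slope of the effects over 4041 genes called with plko.1 was 0.134. Little added HOXB13 may be the cause, as HOXB13 itself was higher by only 0.191 on the log2 scale. A need of HDAC1 and HDAC3 cannot be told apart from it, since the slope divided by the ratio of the HOXB13 changes was 0.923 and the gain of HOXB13 differed along with the deacetylases.

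Fewer genes were called in the hormone-starved LNCaP and PC3 knockdowns than in the LNCaP knockdown. A larger spread between replicates as the whole cause is argued against, as the genes with a mean of at least 5 in 1 group that lay at least 2-fold apart, whatever the test, were 276 in LNCaP, 142 in hormone-starved LNCaP and 23 in PC3 cells. Lower depth is argued against by mean reads in genes of 10.69 M and 10.83 M per library, above the 6.46 M of the LNCaP knockdown. A smaller loss of HOXB13 may be a cause, with a log2 fold change of -0.584 in PC3 cells and -1.04 in hormone-starved cells against -1.23 in the LNCaP knockdown. The cell line and the medium stay open and were not tested.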

How the results depend on the processing

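Limma-voom on the recovered reads and the spread of the hormone-starved libraries were chosen only after the data were seen, and the other alternatives were planned. With the spread of the hormone-starved libraries, the changed genes were 3121 in the LNCaP knockdown, 4065 with WT, 3730 with G84E, 23 between G84E and WT, 3817 with shHDAC1/3, 994 with HOXB13 added to plko.1 cells, 6 in the libraries labelled shHDAC1/3+HOXB13 and 150 in the interaction, and the genes reversed 2289 with WT and 1912 with G84E. With no filter on low values the counts were 752 between G84E and WT, 107 in the libraries labelled shHDAC1/3+HOXB13, 291 in the hormone-starved knockdown and 0 by limma in PC3, where 2769 genes had an unadjusted p under 0.05. Without the variance trend they were 270 between G84E and WT, 11 in the libraries labelled shHDAC1/3+HOXB13, 1006 in the interaction, 650 hormone-starved and 1 in PC3. By limma-voom they were 2589 between G84E and WT, 623 in the libraries labelled shHDAC1/3+HOXB13, 2796 hormone-starved and 937 in PC3. With a replicate block they were 118 in the libraries labelled shHDAC1/3+HOXB13 and 598 in PC3, but replicates with the same number did not deviate together, with correlations from -0.058 to 0.084, so the numbers do not pair the libraries. With only the groups compared, 14 genes passed in the libraries labelled shHDAC1/3+HOXB13.

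The median of the fatty acid synthesis list moved past the test between G84E and WT under quantile normalization (0.032), median ratio scaling (0.026) and limma-voom (0.027), with shHDAC1/3 with no filter (-0.247), and in the libraries labelled shHDAC1/3+HOXB13 under median ratio scaling and limma-voom (both -0.074). With an estimated correlation it was no longer past the test with HOXB13 added to plko.1 cells (-0.126), in the interaction (0.128) and in the hormone-starved knockdown (0.142). KLK3 between G84E and WT turned from 0.46 to -0.066 under quantile normalization, which fixes the values of the highest genes by rank. ACLY with G84E turned from 0.07 to -0.091 after median ratio scaling and -0.092 by limma-voom. The causes for ACLY and of the other changes were not tested.

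Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 201 to 1192 genes between G84E and WT, 2472 to 3918 with HOXB13 added to plko.1 cells, 21 to 124 in the libraries labelled shHDAC1/3+HOXB13, 880 to 1192 in the interaction, 395 to 1151 hormone-starved and 22 to 1838 in PC3, with the libraries named in the report. The counts stayed within 1.5 times at 4812 to 5458 in the LNCaP knockdown, 5211 to 6658 with WT, 4636 to 6251 with G84E and 4950 to 6321 with shHDAC1/3, and the genes reversed were 3752 to 4198 with WT and 3092 to 3641 with G84E. The fatty acid synthesis median was -0.080 to -0.032 in the libraries labelled shHDAC1/3+HOXB13, -0.016 to 0.021 between G84E and WT, 0.103 to 0.197 hormone-starved and -0.049 to -0.011 in PC3. Pseudocounts of 0.1 and 1 left each count within 1.5 times. With each result counted once per alternative, 2028 of 2103 values of named genes and 664 of 691 list results were unchanged. Under every alternative, only 91 of 124 named gene results and 22 of 41 list results stayed unchanged. Of 167 alternative counts of changed genes 53 moved by over 1.5 times, and 0 of the 10 counts stayed within that range throughout. A turn of direction was counted only where the result was called as reported, and a list took its direction from camera. On simulated data false calls were above the nominal 5%, up to 25.5% in the hormone-starved comparison, and depth limits what can be seen in genes with few reads, lowest in the LNCaP knockdown.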

Other observations

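XBP1, which encodes a transcription factor of the unfolded protein response, rose from 107 ± 0.62 to 278 ± 2.9 RPKM with shHOXB13 (1.37 ± 0.023) and fell with added WT (-1.44 ± 0.023) and G84E (-1.23 ± 0.023). HSPA5, the chaperone of the endoplasmic reticulum, rose with shHOXB13 (0.51 ± 0.018) and with shHDAC1/3 (0.72 ± 0.021), and 12 of 16 genes of the unfolded protein response rose and 1 fell with shHOXB13, over all genes and adjusted over the list alone (camera adjusted p = 3.3e-09, adjusted p = 0.034 with an estimated correlation). In the hormone-starved knockdown 1 of these genes rose and 3 fell (1 and 9 adjusted over the list alone; median -0.25, adjusted p = 0.0067, but adjusted p = 0.50 with an estimated correlation), and with HOXB13 added to plko.1 cells 4 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.50), a list that passed as lower only by limma-voom. The fibronectin gene FN1 rose with shHOXB13 (1.73 ± 0.035) but fell with shHDAC1/3 (-1.50 ± 0.029).

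Of 16 genes of the class I HDAC and NCoR complexes, 15 fell with shHOXB13 and none rose (median -0.38, camera adjusted p = 9.1e-05), and 15 rose and none fell with WT (median 0.44, adjusted p = 5.1e-05), with the same counts adjusted over the list alone. With G84E, too, 15 rose and none fell (median 0.36, camera adjusted p = 1.0e-04), over all genes and adjusted over the list alone. The list did not pass with HOXB13 added to plko.1 cells, where 6 rose and none fell, over all genes and adjusted over the list alone (adjusted p = 0.19), or in the hormone-starved knockdown, where none rose and 1 fell (2 adjusted over the list alone; adjusted p = 0.14), but passed in both with no filter on low values and in the latter under quantile normalization too. HDAC2 fell with shHOXB13 from 24.8 ± 0.79 to 14.1 ± 0.48 RPKM (-0.79 ± 0.044), and HDAC3 from 25.8 ± 2.5 to 19.2 ± 0.51 RPKM (-0.42 ± 0.068). HDAC3 rose again with WT (0.41 ± 0.068) and with G84E (0.44 ± 0.068). The median of all genes moved as well, and relative to it the list stood at -0.25 with shHOXB13 and 0.26 with WT. Replication-dependent histone genes went the other way, with 8 of 12 higher with shHOXB13 and none lower, over all genes and adjusted over the list alone (camera adjusted p = 9.1e-05), HIST1H1C among them (1.02 ± 0.052).

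All tests in this paragraph were chosen only after the values were seen. The microRNA gene MIR30A (chromosome 6, 71403551 to 71403621), of 71 bp, had a lowest value of 1587.1 (1128 reads at the fewest) and a highest of 12382.4 in the libraries of sets made with pGIPZ, but at most 6.41 (7 reads) in those made with plko.1. In the knockdown and rescue set it was at 11061.48 and 10807.98 with pGIPZ and at 12382.4 and 12257.41 with shHOXB13. It was lower in the rescue libraries, at 3634.37 and 3350.66 with WT and at 4050.6 and 4076.51 with G84E. Transcription of MIR30A in LNCaP cells is argued against, since the 8 LNCaP libraries made with plko.1 had from 0 to 7 reads of it. A loss of short RNAs in the plko.1 set is argued against too, since the median of 78 other genes of at most 150 bp was 1.146 times that of the LNCaP pGIPZ and shHOXB13 libraries. Reads from the microRNA-30 backbone of pGIPZ may be the source, and no vector sequence was at hand to test this further. If so, the lower values in the rescue libraries leave open a weaker knockdown there, which was not tested.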
